A study of Homo sapiens with 8 samples.

How the data were processed

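RNA of MCF-7 breast cancer cells was measured on Affymetrix oligonucleotide arrays in 2 groups of 4 samples, DMSO controls and cells given 40 uM gamma-tocotrienol for 24 h in medium with 5% serum. Each array took labelled RNA made from 6 ug of total RNA. The labels describe the 4 replicates of a group as biological and as independent experiments. The sample titles of the treated group give the dose as 40 mM, whereas the protocol and the design give 40 uM, which is used here.

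The deposited values were log2 probe set summaries, made by the authors with RMA (robust multi-array average: background correction, quantile normalisation and median polish). RMA is named in the submitters' processing notes, and its software and version are not given in the sources used here. The values were used without further transformation or scaling, and 0 columns of values were left out.

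The table held 22277 probe sets, of which 62 were control probe sets, 19064 named 1 gene, 1043 named several and 2108 were not named here. Of the probe sets with 1 gene, 19052 were found in the reference by Entrez ID. Each gene was represented by the probe set with the highest mean over all 8 arrays among those naming it alone, which gave 11963 genes, 4310 of them with more than 1 probe set. For 5009 genes this probe set had an x or s suffix, which marks probes shared by several transcripts or able to bind other sequences. No genes were filtered by signal. Probe sets with several genes or none were tested apart. HMGCR and LDLR had no probe set of their own in the annotation used, which leaves probe sets unnamed, and were not analysed here.

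Treated and control arrays were compared with limma (linear model and empirical Bayes, two-sided) in R 4.3.3 with limma 3.58.1, and p was adjusted by Benjamini-Hochberg over all genes, with a threshold of 0.05 and, for the counts by size, 2-fold. No covariate was used. Before the data were examined, 29 gene lists were fixed, with 84.4% of the listed names measured. The lists were tested with camera at a preset correlation of 0.01, adjusted over the lists, beside camera with an estimated correlation and fry. List medians per array and measures of RNA quality were compared by an exact two-sided permutation test over the 70 splits, whose smallest p is 0.0286. The number of arrays limits the precision.

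Genes are named by a rule fixed with the lists. It gives the 12 genes with the largest fold change in each direction that passed the test, had no overlap between groups and had a mean in the higher group at or above the median of all genes. It adds 16 genes of interest whatever their result, and up to 4 genes with the smallest adjusted p in each list. Of the 138 genes with a value that the rule gives, 116 are printed; the other 22 come from the lists and none of them passed the test. A further 13 genes are printed in the report to complete small counts, chosen after their values were seen: ATF5, GLA, CXCL8, TM7SF2, HSD17B7, FOXM1, SIAH2, TP53I3, DDB2, TNFRSF10B, BCL2L11, CLDN3 and KRT19. The genes given only in the closing paragraphs were also chosen after their values were seen. The lists of basal and mesenchymal and of blood and endothelial genes stand for cells other than this line.

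The alternatives tried were the mean of a gene's probe sets, probe sets without x or s suffix, every probe set on its own, genes above the median level only, quantile normalisation again, centring on the array median, a trended and robust variance model, array weights, the replicate number as a block, and each array left out in turn. After the data were seen, 3 technical splits of the arrays were added: 2 and 3 clusters by the spike-in controls, and 2 clusters by the 18S and 28S probe sets. The splits were used as a block, and the pairs of clusters also on their own.

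The fit was tested on simulated data of 11963 genes on 4 and 4 arrays. It recovered 55% of genes shifted by 0.5 on the log2 scale and 99% of those shifted by 1, with 0 in the wrong direction, and called 3 of 11723 unchanged genes. Camera called a list of 40 genes shifted by 0.3 and did not call an unshifted list. The simulated genes were independent, so correlation between genes was not covered by this check. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.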

Results

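The series measured messenger RNA levels in MCF-7 cells, an established line of oestrogen-receptor-positive, luminal breast cancer cells. The cells were exposed for 24 h to 40 uM gamma-tocotrienol, a member of the vitamin E family with an unsaturated side chain, or to its vehicle, DMSO. Each group held 4 arrays, described as independent experiments, and each array was an oligonucleotide microarray hybridised with labelled RNA of 1 culture. The log2 values of 22277 probe sets had medians of 6.18 to 6.21 per array. After 1 probe set was chosen for each gene, 11963 genes were tested, and correlations between arrays ran from 0.988 to 0.998. The number of arrays limits the precision of every value below.

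The comparison asked which transcripts gamma-tocotrienol changed in these cells within 24 h, as the design states no narrower aim. The largest measured rise was that of ATF3, a transcription factor of the cellular stress response, from a log2 value of 4.84 ± 0.40 (SD, n = 4) to 8.91 ± 0.86 (SD, n = 4). This was a 16.8-fold difference (log2 fold change 4.07, SE 0.36, limma adjusted p = 0.000465). DDIT3, which encodes the stress factor CHOP, rose 8.29-fold. INHBE, an inhibin subunit, rose 14.7-fold from 3.64, within the range of the dimmest 2393 genes (2.80 to 4.47) and not shown to be above background, so the size of its rise is uncertain. MAFF, a small MAF transcription factor, rose 5.36-fold, the co-chaperone gene DNAJB9 4.54-fold and HERPUD1, a component of endoplasmic-reticulum-associated degradation, 4.36-fold. PHLDA1, GEM, ANG (angiogenin), FKBP14, EGR1 and CAMTA2 rose between 3.53-fold and 4.01-fold. In controls ATF3, MAFF (4.91) and ANG (5.25) lay within the range of the next dimmest 2392 genes (4.47 to 5.94). They were not shown to be above background there, so the sizes of their rises are also uncertain. The falls were smaller. REEP1, a membrane-shaping protein of the endoplasmic reticulum, fell 2.25-fold (log2 fold change -1.17, SE 0.18, adjusted p = 0.00471) and ABCG1, a cholesterol exporter, 2.21-fold. FGFR4, a receptor tyrosine kinase, PPP1R3C, a glycogen-targeting phosphatase subunit, SOX11, MEGF9, RBM14 and MYBL1 fell between 2.00-fold and 2.08-fold. CLIC3, GPER1 (a membrane oestrogen receptor), the replication factor MCM10 and FASN (fatty acid synthase) fell between 1.90-fold and 1.99-fold. Other probe sets changed less for MAFF (0.62 on the log2 scale), FGFR4 (-0.49) and MEGF9 (-0.31). That of FASN, with an x suffix, changed by 0.12. Those of PHLDA1 changed by 0.41 to 2.05, against 2.00 for the probe set used. The 4 control and the 4 treated values of each of these 24 genes did not overlap. MYBL1 lost its call without control replicate 2 and without treated replicate 3, where its adjusted p was highest at 0.063.

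**Figure D1:**
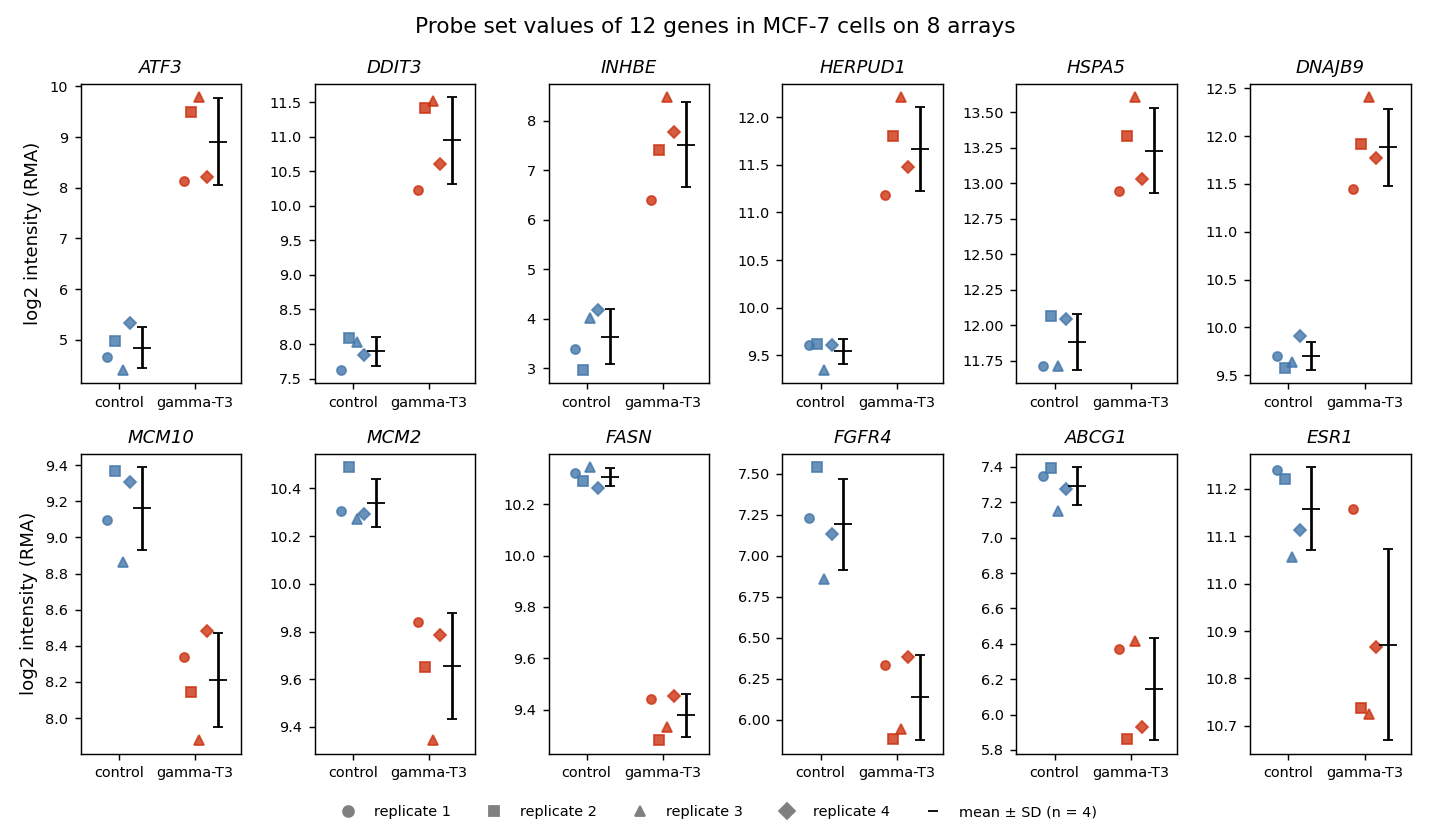
Log2 values of 12 genes (vertical axes, RMA log2 intensity) on the 4 control and 4 gamma-tocotrienol (gamma-T3) arrays, with 1 symbol per replicate number and the mean ± SD (n = 4) beside each group; vertical axes differ between panels and do not start at 0. ATF3 stood at 4.84 in controls and 8.91 in treated cells and FASN at 10.3 and 9.38, while the values of ESR1 (11.2 and 10.9) overlapped.

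In all, 644 genes (5.38% of those tested) were higher and 533 (4.46%) lower after gamma-tocotrienol at an adjusted p below 0.05 (limma, two-sided). Of these, 80 were higher and 9 lower by at least 2-fold. Genes with faint signals were rarely called, 0.334% of the dimmest 2393 genes against 15.8% of the brightest 2393. The numbers changed with the array left out. Without control replicate 1, 375 genes were higher and 214 lower, and without control replicate 2, 367 and 169. They were 353 and 150 without treated replicate 3, 707 and 634 without treated replicate 1, and 617 and 540 without treated replicate 4. A fit on fewer arrays has less power by construction, so a fall need not come from the particular array. Without control replicate 4 and without treated replicate 2, 238 and 243 genes were lower. The 80 genes higher by at least 2-fold became 52 without treated replicate 3, and the 9 lower became 4 without control replicate 4, 2 without treated replicate 2 and 3 without treated replicate 3.

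The arrays also differed in technical signals, of which the spike-in and ribosomal RNA signals split the arrays across the groups. The bacterial spike-in controls split them into control replicates 1 and 2 with treated replicates 1 and 4, and control replicates 3 and 4 with treated replicates 2 and 3. With this split as a block, 664 genes were higher and 564 lower; within the first cluster the counts were 104 and 16, and within the second 135 and 41, each from 2 control and 2 treated arrays. The 18S and 28S ribosomal RNA probe sets were lower on control replicates 1 and 3 and treated replicates 1 and 4 than on the others. With that split as a block, 727 genes were higher and 551 lower; within the low-signal cluster the counts were 42 and 2, and within the high-signal cluster 379 and 378. The difference between 3' and 5' probe sets of GAPDH, a sign of RNA integrity, was -0.08 ± 0.02 in controls and -0.05 ± 0.02 in treated cells (SD, n = 4, exact permutation p = 0.0286, adjusted p = 0.2 over 7 measures). The exact p was 0.0571 without control replicate 4 or without treated replicate 4. For beta-actin the difference was 0.77 ± 0.09 and 0.84 ± 0.08 (SD, n = 4, exact permutation p = 0.286).

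Targets of ATF4 and CHOP, the transcription factors of the integrated stress response, rose as a group. Of 36 measured members 24 rose, 1 fell and 11 did not pass the test, or 28 and 1 adjusted over the list alone. Besides ATF3 and DDIT3, GDF15, a stress-induced cytokine, rose 3.45-fold (log2 fold change 1.79, SE 0.15, adjusted p = 0.000405) and STC2, a secreted glycoprotein, 1.97-fold. ATF4 itself rose 1.67-fold (adjusted p = 0.00468) and TRIB3, a pseudokinase, 1.57-fold (adjusted p = 0.0139). The member that fell was ATF5, by 0.54 on the log2 scale (adjusted p = 0.00751), named because it was the only one. The value of GDF15 came from a probe set with an x suffix, and its other probe set changed by 0.11 on the log2 scale (adjusted p = 0.751 when used in its place). The camera test gave an adjusted p of 6.05e-20 for the list with the preset correlation, and an adjusted p = 0.209 with an estimated correlation. The list's mean log2 fold change was 0.74, and between 0.60 and 0.87 within the 4 technical clusters.

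Genes of protein folding and degradation in the endoplasmic reticulum, known targets of ATF6 and XBP1, also rose. Of 42 measured members 27 rose and none fell (31 and 0 adjusted over the list alone). HSPA5, the main chaperone of this compartment, rose 2.54-fold from 11.9 ± 0.20 to 13.2 ± 0.30 (SD, n = 4, limma adjusted p = 0.0016). DNAJB9 and HERPUD1 are given above, and MANF, a secreted stress-induced factor, rose 2.00-fold. XBP1, whose total transcript the array reads without regard to splicing, stood at 12.3 in both groups (log2 fold change -0.04, SE 0.08, adjusted p = 0.824). For the list the camera adjusted p was 2.7e-21, and the adjusted p = 0.209 with an estimated correlation. Its mean log2 fold change was 0.56, and 0.41 to 0.72 within the technical clusters.

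Genes of vesicle trafficking and the Golgi rose in 20 of 38 cases with none falling (27 and 0 adjusted over the list alone). They included ARF4, a small GTPase of the Golgi (2.09-fold), ARFGAP3, a GTPase-activating protein of ARF proteins (2.15-fold), BET1, a SNARE of transport vesicles (2.05-fold), and CREB3L2, a membrane-bound transcription factor (1.59-fold), with adjusted p between 0.0015 and 0.00222. Camera gave this list an adjusted p of 6.05e-20, and adjusted p = 0.209 with an estimated correlation. It shares 4 genes with that of the endoplasmic reticulum. The mean log2 fold change was 0.46, and 0.34 to 0.59 within the technical clusters.

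The treated arrays did not respond alike. The mean of these 3 list medians, relative to controls, was 0.32 on treated replicate 1, 0.55 on replicate 2, 0.74 on replicate 3 and 0.39 on replicate 4, against -0.03 to 0.04 on the control arrays. Treated replicates 2 and 3 also carried the higher ribosomal RNA signal, and they were the treated arrays of the second spike-in cluster. The size of the response could therefore not be told apart from either technical split. The technical clusters held only 2 different pairs of treated arrays, replicates 1 and 4 and replicates 2 and 3. No overlap between 4 and 4 arrays occurs by chance in 2.86% of splits, and the exact permutation p of each list median was 0.0286, the smallest the design allows, or 0.0829 after adjustment over 29 lists.

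**Figure D2:**
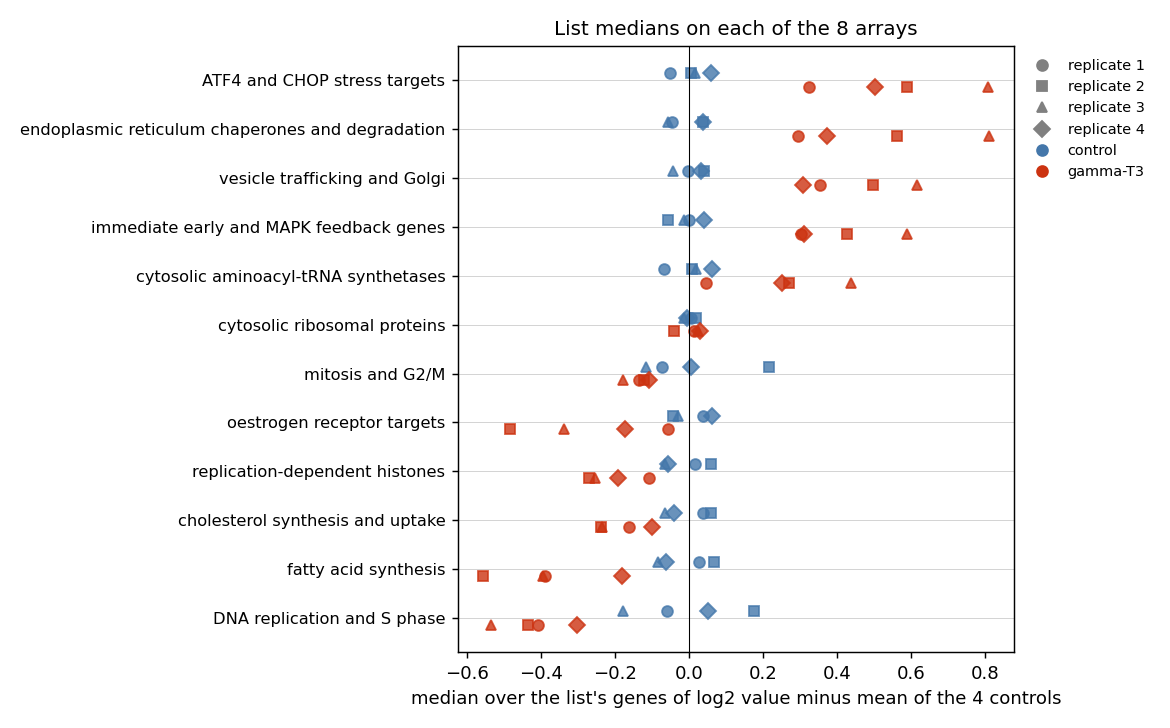
Median over the genes of 12 lists of the log2 value minus the mean of the 4 controls (horizontal axis), for each control and gamma-tocotrienol (gamma-T3) array, with 1 symbol per replicate number. In the list of ATF4 and CHOP targets the treated arrays lay between 0.32 and 0.81 and the controls between -0.05 and 0.06, and in that of DNA replication between -0.54 and -0.30 against -0.18 and 0.18.

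Immediate early genes and feedback regulators of MAPK signalling rose in 16 of 31 cases, with none falling (18 and 1 adjusted over the list alone). EGR1, a zinc finger transcription factor induced by growth signals, rose 3.70-fold and ETV5, an ETS factor, 2.80-fold (adjusted p = 0.00167 for both), with log2 fold changes of 0.93 and 0.46 on the other probe sets of ETV5. ATF3, also a member, and PHLDA1 are given above. For this list camera gave an adjusted p of 1.01e-12, and the adjusted p = 0.209 with an estimated correlation. MYC rose 1.39-fold (adjusted p = 0.0184), a call lost without control replicate 4 and without treated replicate 3 (adjusted p up to 0.0615). Among NF-kB and inflammatory genes 5 of 24 rose (7 adjusted over the list alone) and none fell: IRF1 (1.51-fold), ICAM1 (1.34-fold), IL6 (1.40-fold), CCL20 (1.34-fold) and, named because so few passed, CXCL8 (1.94-fold). CCL20 (3.87 in controls and 4.29 in treated cells) lay among the dimmest genes and IL6 (4.24 and 4.73) at their edge. IL6, CCL20 and CXCL8 lost their calls in 6 or 7 of the 8 fits with 1 array left out (adjusted p up to 0.139). For this list the camera adjusted p was 0.0284, and the adjusted p = 0.396 with an estimated correlation; it was 0.0548 without control replicate 2 and 0.0705 without treated replicate 4. Within the technical clusters its mean log2 fold change was 0.11 to 0.19, with camera adjusted p of up to 0.102.

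Of 16 cytosolic aminoacyl-tRNA synthetases 7 rose and none fell (8 and 0 adjusted over the list alone). GARS1 rose by 0.59 on the log2 scale, WARS1 1.62-fold, IARS1 1.34-fold and SARS1 1.38-fold (adjusted p between 0.0117 and 0.0229). Only GARS1 of these 4 kept its call whichever array was left out; SARS1 lost it in 5 of 8 such fits (adjusted p up to 0.071). As a list they had a camera adjusted p of 0.000233, and an adjusted p = 0.415 with an estimated correlation. In the list of autophagy and lysosome genes 7 of 39 rose and 1 fell (9 and 1 adjusted over the list alone). WIPI1, which acts in the formation of autophagosomes, rose 2.44-fold (adjusted p = 0.00115), MAP1LC3B, the autophagosome marker LC3, 2.37-fold, the lysosomal lipase LIPA 1.35-fold and GABARAPL1 1.38-fold. GLA, a lysosomal galactosidase named as the only one to fall, decreased by 0.54 on the log2 scale, with its call lost in 6 of the 8 leave-one-out fits (adjusted p up to 0.0874). The autophagy list had a camera adjusted p of 0.00133, and an adjusted p = 0.209 with an estimated correlation.

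Genes of DNA replication and S phase fell. Of 47 measured members 27 fell and none rose, or 39 and 0 adjusted over the list alone. MCM10 fell 1.93-fold from 9.16 ± 0.23 to 8.21 ± 0.26 (SD, n = 4, limma adjusted p = 0.00468). MCM2 and MCM5, subunits of the replicative helicase, fell 1.61-fold and 1.58-fold, and GINS1, of the GINS complex, 1.56-fold (adjusted p between 0.00632 and 0.00754). The replication list had a camera adjusted p of 6.05e-20, and an adjusted p = 0.227 with an estimated correlation. The mean log2 fold change of -0.40 was between -0.57 and -0.23 within the technical clusters. In the mitosis list 5 of 48 members fell and none rose, in the full count and adjusted over the list alone. These were CDC25A (1.52-fold), the proliferation marker MKI67 (1.38-fold), SPC25 (1.58-fold), CENPM (1.32-fold) and, named as the last of the 5, FOXM1 (1.28-fold). The other probe sets of MKI67 changed by -0.30 to -0.39 on the log2 scale and that of CDC25A by -0.27. None of these passed when every probe set was tested. MKI67 lost its call without treated replicate 3 (adjusted p = 0.0519), and SPC25, CENPM and FOXM1 lost their calls in 5 or 6 of the 8 leave-one-out fits (adjusted p up to 0.109). The mitosis list had a camera adjusted p of 0.000273, and an adjusted p = 0.684 with an estimated correlation; it was 0.0628 without control replicate 2. Within the low ribosomal RNA cluster the mean was -0.01 with the test turned upward (adjusted p = 0.996), and within the second spike-in cluster the adjusted p was 0.0835. The median of the replication list lay 0.27 below that of the mitosis list relative to controls, lower on 4 of 4 treated arrays (exact permutation p = 0.0286, adjusted p = 0.0571 over 4 list contrasts). Among replication-dependent histones 4 of 27 fell and none rose (12 and 0 adjusted over the list alone): H3C8, H2AC6, H2BC6 and H2BC9, by 1.22-fold to 1.34-fold. H2BC6 and H2BC9 lost their calls in 6 of the 8 leave-one-out fits each (adjusted p up to 0.102). H3C8, H2BC6 and H2BC9 were read by probe sets with an x suffix, which can bind other sequences, so these may not be separate changes. Camera gave the histone list an adjusted p of 0.000181, and an adjusted p = 0.227 with an estimated correlation. Neither CDKN1A, the p21 inhibitor of the cell cycle (log2 fold change 0.01, adjusted p = 0.991), nor CCND1, cyclin D1 (log2 fold change -0.43, SE 0.15, adjusted p = 0.0878), passed the test. Without treated replicate 1 CCND1 was called lower (log2 fold change -0.59, adjusted p = 0.00744). The sign of CDKN1A turned without control replicate 1 (-0.06), control replicate 2 (-0.07), treated replicate 3 (-0.06) or treated replicate 4 (-0.04).

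Fatty acid synthesis genes, known targets of SREBP1, fell in 6 of 12 cases and none rose (8 and 0 adjusted over the list alone). FASN fell from 10.3 ± 0.04 to 9.38 ± 0.08 (SD, n = 4, log2 fold change -0.93, limma adjusted p = 0.000405). SREBF1, which encodes SREBP1, fell 1.89-fold, SCD, the stearoyl-CoA desaturase, 1.70-fold, and ACACA, acetyl-CoA carboxylase, 1.38-fold. As a list they had a camera adjusted p of 4.61e-06, and an adjusted p = 0.209 with an estimated correlation. Cholesterol synthesis and uptake genes, known targets of SREBP2, fell in 5 of 22 cases and 1 rose (8 and 2 adjusted over the list alone). EBP, ACAT2, FDPS and LSS, all enzymes of the pathway, fell between 1.33-fold and 1.47-fold; the last of the 5, TM7SF2, fell 1.32-fold, and HSD17B7 rose 1.37-fold, both named because they completed these counts. HSD17B7 lost its call in 6 of the 8 leave-one-out fits (adjusted p up to 0.0786), LSS in 3 (up to 0.058) and TM7SF2 without control replicate 2 (0.0576). Camera gave the cholesterol list an adjusted p of 0.00453, and an adjusted p = 0.396 with an estimated correlation. Within the low ribosomal RNA cluster it was 0.102. The median of the fatty acid list lay 0.19 below that of the cholesterol list relative to controls (exact permutation p = 0.0286, adjusted p = 0.0571). HMGCR and LDLR, further genes of the cholesterol list, had no probe set of their own in the annotation used and were not analysed here.

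Known targets of the oestrogen receptor fell in 9 of 33 cases and rose in 2 (16 and 4 adjusted over the list alone). NHERF1, a scaffold protein, fell 1.58-fold, FKBP4, a co-chaperone of steroid receptors, 1.52-fold, the receptor tyrosine kinase RET 1.57-fold and OLFM1 1.65-fold, with adjusted p between 0.00365 and 0.0145. The other probe sets of OLFM1 changed by -0.22 and -0.05 on the log2 scale. The members that rose were MYC and SIAH2 (1.27-fold), the latter named for that reason; SIAH2 lost its call in 4 of the 8 leave-one-out fits (adjusted p up to 0.0703). ESR1, which encodes oestrogen receptor alpha, was 11.2 ± 0.09 in controls and 10.9 ± 0.20 in treated cells (SD, n = 4, limma adjusted p = 0.107), and was called lower without treated replicate 1 (log2 fold change -0.38, adjusted p = 0.018). PGR (log2 fold change 0.01, adjusted p = 0.981) and TFF1 (0.02, adjusted p = 0.902), further targets of the receptor, did not pass the test. PGR stood at 4.60 in controls, just above the dimmest 2393 genes, and TFF1 at 14.1, near the highest value of every array. A fall of PGR or a rise of TFF1 could therefore have been missed. The sign of PGR turned without control replicate 1 (-0.05), treated replicate 1 (-0.05) or treated replicate 4 (-0.09). The list of oestrogen receptor targets had a camera adjusted p of 0.000273, and an adjusted p = 0.396 with an estimated correlation. Within the low ribosomal RNA cluster it was 0.102.

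Markers of luminal identity went both ways: 4 of 21 rose and 2 fell (6 and 3 adjusted over the list alone). AGR2, a protein disulphide isomerase of secretory cells, rose 2.34-fold, the splicing factor ESRP1 1.55-fold and ELF3 1.36-fold, while keratin 8 (KRT8) fell 1.23-fold. CLDN3 (1.25-fold higher) and KRT19 (1.29-fold lower) were the others, named to complete the counts. The controls of AGR2 followed the spike-in split, at 11.6 on replicates 1 and 2 and 10.8 on replicates 3 and 4. The size of its rise is therefore uncertain. ELF3, KRT8, CLDN3 and KRT19 lost their calls in 3, 6, 7 and 7 of the 8 leave-one-out fits (adjusted p up to 0.13). The mean of the list was 0.04, its median -0.10 and the camera test pointed down (adjusted p = 0.88); it pointed up without control replicate 1 (0.909), control replicate 2 (0.822), treated replicate 2 (0.699) or treated replicate 4 (0.997). Markers of other cells gave few calls. Among basal and mesenchymal markers 1 of 20 passed the test, TGFBI, an extracellular matrix protein (1.79-fold higher, adjusted p = 0.00262), and among blood and endothelial markers 1 of 20, CORO1A (1.35-fold lower, adjusted p = 0.0111); both counts were the same adjusted over the list alone. Their camera adjusted p were 0.767 and 0.872. The median of the blood list was 0.04, its mean -0.004 and its test pointed up; within the technical clusters its test turned from down (adjusted p = 0.0123, low ribosomal RNA signal) to up (0.0319, high signal). It also pointed down without control replicate 2 (0.822), control replicate 4 (0.756) or treated replicate 2 (0.621).

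Pro-apoptotic genes rose in 5 of 27 cases and 1 fell (5 and 2 adjusted over the list alone). HRK rose 2.65-fold (adjusted p = 0.00262; 0.71 and -0.03 on the log2 scale for its other probe sets), PMAIP1, which encodes NOXA, 1.64-fold and caspase 9 (CASP9) 1.22-fold, while caspase 6 (CASP6) fell 1.61-fold. BCL2L11, which encodes BIM (1.68-fold), and the death receptor TNFRSF10B (1.33-fold) completed the count. The call was lost in 1 of the 8 leave-one-out fits for PMAIP1, in 3 for BCL2L11 and in 4 for CASP9 and TNFRSF10B (adjusted p up to 0.0771). Anti-apoptotic genes rose in 4 of 15 cases and none fell (4 and 2 adjusted over the list alone): XIAP (1.75-fold, adjusted p = 0.00995, and 0.36 on the log2 scale for its other probe set), CFLAR (1.33-fold), BIRC2 (1.25-fold) and BCL2L2 (1.24-fold). The last 3 lost their calls in 6 or 7 of the 8 leave-one-out fits (adjusted p up to 0.132), and CFLAR changed by -0.04 on the log2 scale over the mean of its probe sets. BCL2 did not pass the test (log2 fold change -0.25, SE 0.12, adjusted p = 0.213). Neither list passed the camera test (adjusted p = 0.236 and 0.58). The pro-apoptotic list had a mean of 0.11 and a median of 0.01, the anti-apoptotic list a mean of 0.05 and a median of -0.06. The difference of the pro-apoptotic minus the anti-apoptotic list median was -0.03 between the groups (exact permutation p = 0.543).

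Targets of p53 also went both ways, with 4 of 21 rising and 3 falling (5 and 3 adjusted over the list alone). GADD45A, a growth arrest gene, rose 2.64-fold (adjusted p = 0.00262) and the repair gene XPC 1.37-fold; GDF15 and TNFRSF10B, above, were the others. TRIAP1 fell 1.29-fold, TP53I3 1.39-fold and DDB2 1.32-fold, the last 2 named to complete the count and lost in 5 and 6 of the 8 leave-one-out fits (adjusted p up to 0.139). For the p53 list the camera adjusted p was 0.767. Of 27 NRF2 targets 4 rose and none fell (5 and 3 adjusted over the list alone): SLC7A11, the cystine transporter (2.37-fold, adjusted p = 0.00594), the autophagy receptor SQSTM1 (1.27-fold), UGDH (1.37-fold) and MAFG (1.37-fold), the last 3 lost in 5 or 6 of the 8 leave-one-out fits (adjusted p up to 0.11). SLC7A11 is also a member of the list of ATF4 and CHOP targets. HMOX1, haem oxygenase 1, was 6.4 ± 0.02 in controls and 7.04 ± 0.46 in treated cells (SD, n = 4, limma adjusted p = 0.0516), and was called without treated replicate 1 (log2 fold change 0.85, adjusted p = 0.00136). The NRF2 list had a mean of 0.03, a median of -0.06 and a camera test pointing down (adjusted p = 0.824), or up without control replicate 2 (0.822), treated replicate 1 (0.667) or treated replicate 2 (0.975). In the list of heat shock proteins, which was fixed as cytosolic but also holds mitochondrial chaperones, 1 of 20 rose and 3 fell (3 and 5 adjusted over the list alone). DNAJA1 fell 1.37-fold and STIP1 1.25-fold, as did FKBP4 above, while HSPA9, a mitochondrial chaperone, rose 1.25-fold; STIP1 lost its call without control replicate 2 (adjusted p = 0.0589) and HSPA9 in 7 of the 8 leave-one-out fits (up to 0.13). For this list camera gave an adjusted p of 0.0667, and 0.0123 without control replicate 1, 0.0341 without control replicate 3, 0.0178 without treated replicate 3 and 0.0317 without treated replicate 4. Within the ribosomal RNA clusters it was 0.996 (low signal, pointing up) and 0.0179 (high signal, pointing down).

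The remaining lists held few changed genes. In the mitochondrial oxidative phosphorylation list 4 of 52 genes fell (0 adjusted over the list alone) and none rose: ATP5MC3, NDUFS6, NDUFA8 and NDUFB3, by 1.19-fold to 1.23-fold, each lost in 7 of the 8 leave-one-out fits (adjusted p up to 0.136). Camera gave that list an adjusted p of 0.000233, and an adjusted p = 0.415 with an estimated correlation. No member passed limma's test among 10 metallothionein and metal response genes (mean log2 fold change -0.23, camera adjusted p = 0.00812, and adjusted p = 0.396 with an estimated correlation) or among 27 proteasome subunits (mean -0.09, camera adjusted p = 0.0172, and adjusted p = 0.684 with an estimated correlation). The proteasome list no longer passed without control replicate 2 (0.062), treated replicate 1 (0.113) or treated replicate 2 (0.079), nor within the second spike-in cluster (0.136) or the low ribosomal RNA cluster (0.188). For the metallothionein list the value was 0.0591 within the second spike-in cluster and 0.0653 within the high ribosomal RNA cluster. Some of its members were read by probe sets with an x suffix, which can bind other sequences, so these may not be separate changes. Among 49 cytosolic ribosomal proteins no member passed either (mean 0.01, camera adjusted p = 0.706). Ribosome biogenesis and MYC targets rose in 2 and fell in 2 of 31 cases (3 and 2 adjusted over the list alone): MYC and RRP12 (1.56-fold) rose, UTP20 (1.44-fold) and MRTO4 (1.22-fold) fell, and the camera adjusted p was 0.58. RRP12 and MRTO4 lost their calls in 4 of the 8 leave-one-out fits (adjusted p up to 0.0692). Of 35 genes of glycolysis and the hypoxia response 4 rose and none fell, also adjusted over the list alone: KDM3A (1.73-fold), VEGFA (1.71-fold), BHLHE40 (1.40-fold) and DDIT4 (1.81-fold), the last lost without treated replicate 3 (adjusted p = 0.0538). DDIT4 also belongs to the list of ATF4 and CHOP targets. The glycolysis list had a mean of 0.03, a median of -0.04 and a camera test pointing down (adjusted p = 0.999). The camera adjusted p reached 0.0176 without treated replicate 1. The test pointed up without control replicate 1 (0.357), treated replicate 2 (0.681), treated replicate 3 (0.603) or treated replicate 4 (0.548). Of 32 interferon-stimulated genes 1 rose, ISG20, an exonuclease (2.01-fold, adjusted p = 0.00365), also adjusted over the list alone; the camera adjusted p of 0.474 was 0.0359 without control replicate 4, and 0.932, pointing up, without control replicate 1. Within the spike-in clusters it was 0.00379 (first, down) and 0.742 (second, up). Among 25 targets of lipid and xenobiotic nuclear receptors PLIN2, a lipid droplet protein, rose 1.61-fold, and ABCG1, above, and MYLIP, a ubiquitin ligase of the LDL receptor, fell (by 0.68 on the log2 scale for MYLIP), with the same counts adjusted over the list alone. PLIN2 and MYLIP lost their calls in 2 and 7 of the 8 leave-one-out fits (adjusted p up to 0.13). The list had a mean of -0.05, a median of 0.02 and a camera test pointing up (adjusted p = 0.867), or down without control replicate 2 (0.822).

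**Figure D3:**
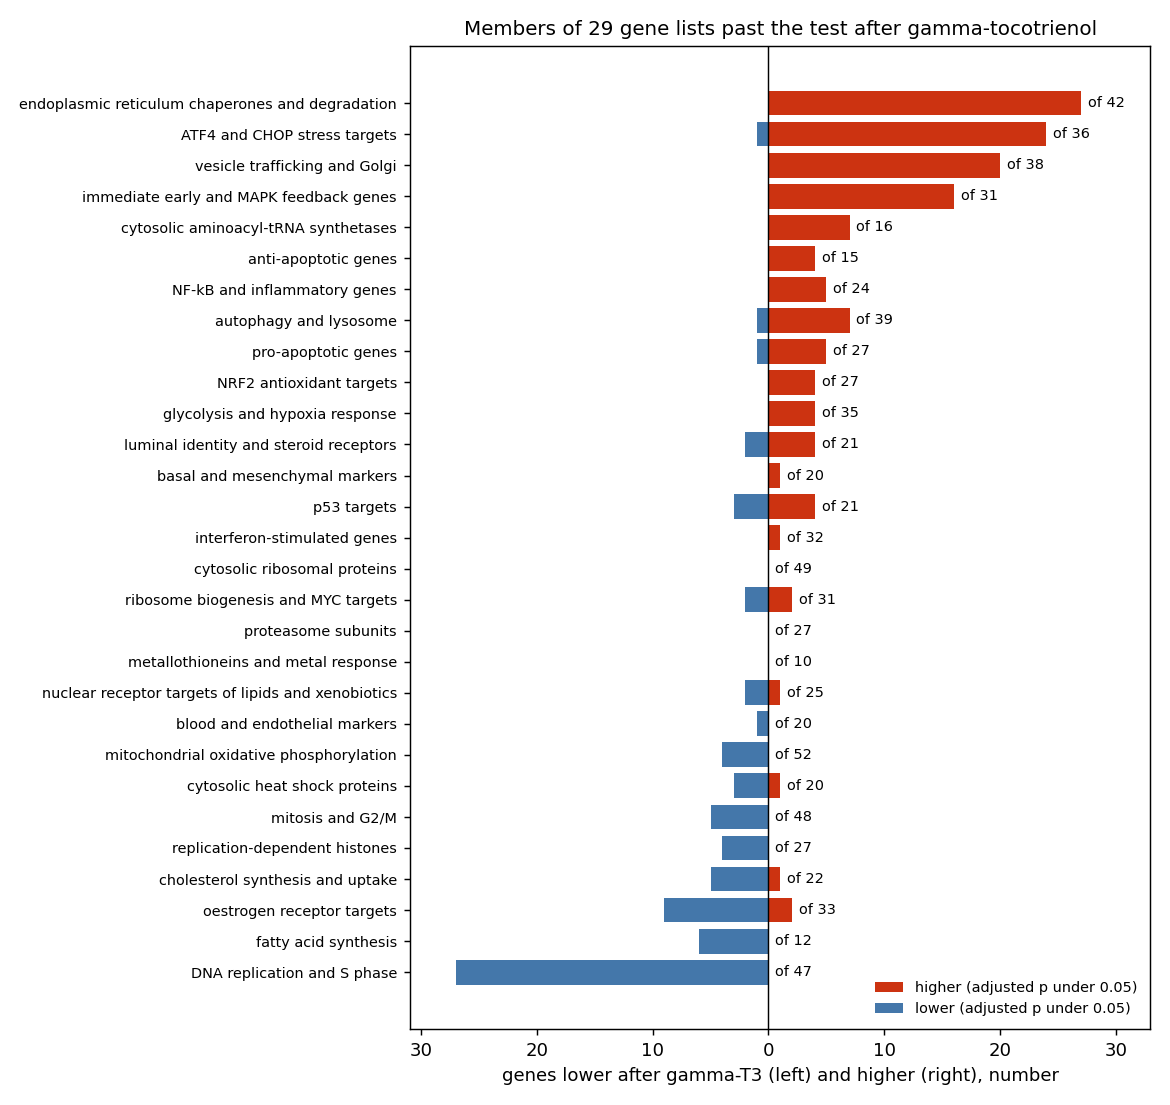
Number of genes in each of 29 lists that were higher (right bars) or lower (left bars) after gamma-tocotrienol (gamma-T3) at a limma adjusted p below 0.05, with the number measured beside each bar. The longest bars belong to the endoplasmic reticulum list (27 of 42 higher) and the DNA replication list (27 of 47 lower).

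Over the 29 lists, camera with a preset correlation of 0.01 passed 16, 7 upward and 9 downward, none passed with the correlation estimated from the data, and 10 passed fry, which tests whether a list moves on balance 1 way without comparing it with other genes. Other splits of the same 8 arrays gave up to 17 lists past the preset test. The split with 17 set control replicates 1, 2 and 4 with treated replicate 1 against the remaining arrays. Such an uneven split keeps part of the difference between the groups. The number of lists therefore cannot decide whether that test alone separated the groups. Of the 35 splits, the real one alone gave so small a camera p for ATF4 and CHOP targets, endoplasmic reticulum chaperones, vesicle trafficking, immediate early genes and fatty acid synthesis. A p as small came from 2 splits for histones and for autophagy, from 3 for tRNA synthetases, DNA replication and oxidative phosphorylation, from 5 for cholesterol synthesis and for NF-kB, from 6 for metallothioneins, from 9 for oestrogen receptor targets, from 12 for proteasome subunits and from 18 for mitosis, the real split included.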

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

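The tests of the stress response size, of zinc finger genes and of single lists over other splits of the arrays were chosen after the results were seen; the tests of the gene counts and of the list count over other splits were planned.

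In several genes 1 array stood far from the other 3 of its group. Among 330 groups of 4 examined 11 did so, and chance flags about 1 in 20 groups, or 16.5 here. HERPUD1 was 9.348 on control replicate 3 and at least 9.605 on the other controls. RBM14 was 8.734 on control replicate 4 and at most 8.642 on the others. STC2 was 7.647 on control replicate 1 against at most 7.405. IARS1 was 11.44 on control replicate 1 against at least 11.63. MCM2 was 10.49 and H3C8 9.39 on control replicate 2, against at most 10.31 and 9.183 on the other controls. NDUFB3 was 10.75 and CLDN3 10.69 on control replicate 4, against at least 10.89 and 10.84. TNFRSF10B was 9.135 on treated replicate 3 against at most 8.81. The difference of 3' and 5' probe sets was -0.1164 for GAPDH on control replicate 4, against at least -0.07521 on the other controls, and 0.7174 for beta-actin on treated replicate 2, against at least 0.8741 on the other treated arrays.

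Probe sets outside the gene comparison also changed. Of 3151 probe sets with several genes or none, 69 were higher and 70 lower at a limma adjusted p below 0.05. Of these, 35 higher and 43 lower ones are not named here, with log2 fold changes from -0.88 to 2.43.

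The treated arrays differed in the size of the stress response: the mean of the 3 stress list medians was 0.55 and 0.74 on treated replicates 2 and 3, with high ribosomal RNA signal, and 0.32 and 0.39 on replicates 1 and 4. Ribosomal RNA that adds to the signal of both groups was argued against as the whole source, since controls with high and low signal differed by 0.0664 and treated arrays by 0.288. The span of the spike-in ladder on the low arrays was 0.955 of that on the high ones, against 0.555 for the stress response. This cannot decide whether signal was compressed on some arrays, since quantile normalisation had already given all arrays nearly the same distribution. Ribosomal RNA that scales the change, which controls without a response cannot show, and dilution with untreated RNA stay open. So do differences between the independent experiments and between the spike-in clusters, which were not tested. Treated replicates 1 and 4 shared the first spike-in cluster, and replicates 2 and 3 the second. Scaling and dilution were tested on 44 falling and 79 rising genes. The value was the median share of the replicate 2 and 3 change kept by falling genes minus that kept by rising genes. The genes were chosen for their change on replicates 2 and 3, which can bias the shares. The 95% intervals resample genes and do not measure spread between arrays. The result depended on the controls used. Against all controls it was 0.0641 for scaling (log2 values, replicates 1 and 4 together, -0.000797 to 0.136). For dilution (unlogged values) it was 0.357 on replicate 1 (0.265 to 0.464) and 0.0536 on replicate 4 (-0.0133 to 0.117). Against controls of the same ribosomal RNA cluster these were -0.247 (-0.325 to -0.176), 0.0768 (-0.0161 to 0.189) and -0.274 (-0.361 to -0.19).

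Most of the 235 zinc finger genes with a ZNF symbol were not called, and their median log2 fold change was 0.00427 (-0.0106 over all genes), but among the called ones 22 rose and 2 fell, against 622 and 531 of the other genes (Fisher exact p = 0.000114, adjusted p = 0.00194 over 17 symbol families examined after the data were seen). The largest rises were those of ZNF222 (2.37-fold), ZNF165 (2.26-fold) and ZNF365 (2.23-fold). Fisher's test and the random sets below take genes as independent, although all calls come from the same arrays. The correlation estimated in the fixed lists ran from 0.0267 (anti-apoptotic genes) to 0.55 (glycolysis). It was not estimated for zinc finger genes, so these p may be too small. Of the 65 such genes above the median level and without x or s suffix, 11 rose and 2 fell. Among other such genes 251 rose and 235 fell (Fisher exact p = 0.0229). If genes are independent, this argues against dim or cross-hybridising probe sets. Of random sets of the same levels 0.22% held as many genes higher, with a median of 12. On the same condition, this argues against signal level. Gamma-tocotrienol as the source of the calls is a hypothesis found and tested on the same data.

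Other splits of the 8 arrays into 4 and 4 were tested, 35 in all. Only the real split reached the 644 higher genes, the 533 lower genes and the 80 and 9 with at least 2-fold change. Any other split gave at most 1 gene. A share of 1 in 35 is the smallest the design allows, so chance can be excluded for these counts only at that level. Every other split mixed control and treated arrays, which adds the difference between the groups to the spread. Few calls would then be found in any case, so the distance from 644 to 1 does not measure strength. For the 16 lists past the preset test this comparison cannot decide on chance. Of the 35 splits 4 gave as many, the real one included. The others were uneven in their controls. They joined control replicates 1, 2 and 4 with treated replicate 1 (17 lists), and control replicate 1 with treated replicates 1, 2 and 3 (16) or 1, 2 and 4 (16). Uneven splits keep part of the difference between the groups. The splits by spike-in and by ribosomal RNA signal, with equal numbers of controls on both sides, gave 15 each. For single lists the number of splits with as small a camera p was 1 for ATF4 and CHOP targets (real p 8.34e-21, smallest other 9.37e-17), 1 for endoplasmic reticulum chaperones (9.31e-23, 1.29e-16), 1 for vesicle trafficking (5.47e-21, 5.84e-15), 1 for immediate early genes (1.74e-13, 2.34e-09) and 1 for fatty acid synthesis (9.55e-07, 4.97e-06). Chance can be excluded as the source of these 5 camera p only with each list taken alone: 1 of 35 is the smallest share the design allows and was not adjusted over the 16 lists. The exact permutation p of the array medians was 0.0829, adjusted over 29 lists, for these 5 and alike for DNA replication, histones, cholesterol synthesis, oestrogen receptor targets and NF-kB. Chance cannot be excluded for the camera p of histones (2 splits, 4.38e-05, 3.25e-05), autophagy (2, 0.000552, 8.31e-06) and tRNA synthetases (3, 7.23e-05, 1.62e-08). Nor can it for DNA replication (3, 6.63e-21, 2.42e-25), oxidative phosphorylation (3, 6.95e-05, 5.89e-07) and cholesterol synthesis (5, 0.00203, 1.56e-05). The same holds for NF-kB (5, 0.0157, 0.001), metallothioneins (6, 0.00392, 3.75e-06) and oestrogen receptor targets (9, 9.75e-05, 4.55e-08). It also holds for proteasome subunits (12, 0.00889, 3.59e-07) and mitosis (18, 0.000104, 3.87e-18). For the lists where chance cannot be excluded, it was not examined whether the smaller p came from uneven splits. Those keep part of the difference between the groups, so the test cannot decide on chance for these lists. These statements concern the camera p and not the called members (27 lower for DNA replication). The limit of those members is that of the gene counts above.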

How the results depend on the processing

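The technical splits of the arrays, the cluster comparisons and the leave-outs of RNA quality were chosen after the results were seen; the other alternatives were planned. For a result that changed, the cause was not tested, except that fits on fewer arrays have less power by construction. Only 0.334% of the dimmest genes were called, and whether low signal over background caused this was not tested.

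All 1177 called genes kept their direction in each fit on fewer arrays or with a block, which their choice on the same arrays nearly ensures. On other probe sets not all did: 1153 of the 1177 had the same direction with probe sets without x or s suffix, and 1176 with the mean of probe sets. Over the 8 fits with 1 array left out, the genes higher numbered 353 to 707 (644 with all arrays), the genes lower 150 to 634 (533), those higher at least 2-fold 52 to 91 (80) and those lower at least 2-fold 2 to 13 (9). With the replicate number as a block they were 507, 351, 79 and 9. The data did not show that the numbers pair the samples: the correlations of same-number samples were 0.291, -0.126, -0.308 and 0.122, with 2 of 4 over 0.1, and 1 of 4 controls and 2 of 4 treated samples correlated best with their own number. The highest correlations of control with treated samples joined unlike numbers. They were 0.502 for control replicate 3 with treated replicate 2 and 0.408 for control replicate 4 with treated replicate 3. Each of these pairs formed a cluster of its own when the spike-in controls were cut into 3 clusters. With the replicate number as a block, the 3' and 5' difference of GAPDH had a sign-flip exact p of 0.125. In the same setting the heat shock list passed (camera adjusted p = 0.0444) and the glycolysis list turned (0.929). Among genes above the median level 835 were lower, and 4 lower at least 2-fold, as also with the mean of probe sets (4) and with array weights (4). With 3 spike-in clusters as a block 945 genes were higher and 955 lower. Genes higher and lower, and both with at least 2-fold change, were 104, 16, 30 and 3 in the first spike-in cluster, 135, 41, 99 and 19 in the second, 42, 2, 23 and 1 in the low ribosomal RNA cluster and 379, 378, 110 and 38 in the high one.

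The 16 lists past the preset test kept direction and side of the threshold in 359 of 400 combinations with an alternative, lost the call in 40 and turned in 1. With an estimated correlation the adjusted p was 0.209 for ATF4 and CHOP targets, endoplasmic reticulum chaperones, fatty acid synthesis, autophagy, immediate early genes and vesicle trafficking. It was 0.227 for DNA replication and histones, 0.396 for cholesterol synthesis, oestrogen receptor targets, NF-kB and metallothioneins, 0.415 for tRNA synthetases and oxidative phosphorylation, and 0.684 for mitosis and proteasome subunits. With fry it was 0.0632 for tRNA synthetases, 0.237 for mitosis, 0.0506 for oestrogen receptor targets and NF-kB, 0.125 for proteasome subunits and 0.0624 for metallothioneins, and lists that turned were glycolysis (0.982), nuclear receptor targets (0.945) and blood markers (0.982).

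In the low ribosomal RNA cluster calls were lost for cholesterol synthesis, oestrogen receptor targets and NF-kB (each 0.102) and proteasome subunits (0.188). The direction turned there for NRF2 (0.864), heat shock proteins and mitosis (both 0.996), luminal markers (0.144), ribosome biogenesis (0.952), glycolysis (0.421), nuclear receptor targets (0.639) and blood markers (0.0123), and for XBP1 (log2 fold change 0.0388) and CDKN1A (-0.0776). In the high cluster metallothioneins lost the call (0.0653), heat shock proteins (0.0179) and blood markers (0.0319) passed, and p53 targets (0.714), anti-apoptotic genes (0.859), ribosomal proteins (0.642), PGR (-0.317) and TFF1 (-0.0257) turned. In the second spike-in cluster calls were lost for mitosis (0.0835), proteasome subunits (0.136), NF-kB (0.0892) and metallothioneins (0.0591), and NRF2 (0.445), p53 targets (0.845), interferon genes (0.742), nuclear receptor targets (0.76), basal markers (0.986), CDKN1A (-0.145) and PGR (-0.309) turned. In the first, interferon genes passed (0.00379) and glycolysis (0.428) and blood markers (0.808) turned.

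With the mean of probe sets heat shock proteins passed (0.0226) and nuclear receptor targets (0.809) and CFLAR (-0.0437) turned. The genes CASP9, HSPA9, ELF3 and PLIN2 lost their calls in that setting. With probe sets without x or s suffix proteasome subunits lost the call (0.0885), heat shock proteins passed (0.0146), and p53 targets (0.743), anti-apoptotic genes and glycolysis (both 0.956) and CFLAR (-0.0351) turned. Calls of the genes GDF15, NDUFB3, HSPA9, ELF3 and RRP12 were lost there. Among genes above the median level proteasome subunits (0.0724) and NF-kB (0.775) lost the call, heat shock proteins passed (0.0434), luminal markers (0.982) and glycolysis (0.937) turned, and blood markers gave no value. After quantile normalisation luminal markers (0.946), glycolysis (0.896) and CDKN1A (-0.00383) turned.

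With 1 array left out the adjusted p ran from 0.443 to 0.975 for NRF2, 0.0123 to 0.395 for heat shock proteins, 1.81e-07 to 0.0628 for mitosis, 0.384 to 0.997 for luminal markers, 0.00181 to 0.113 for proteasome subunits, 0.0176 to 0.920 for glycolysis, 0.0133 to 0.0705 for NF-kB, 0.0359 to 0.951 for interferon genes, 0.606 to 0.975 for nuclear receptor targets and 0.255 to 0.822 for blood markers. The exact p ran from 0.0286 to 0.0571 for the GAPDH difference, 0.457 to 0.857 for 18S, 0.6 to 0.971 for 28S, 0.486 to 0.971 for the spike-in mean, 0.257 to 0.971 for the spike-in span and 0.543 to 0.943 for the interquartile range. The log2 fold change of CDKN1A ran from -0.069 to 0.0933 and that of PGR from -0.0921 to 0.155. Of the 121 called genes printed in the report, 75 kept the call whichever array was left out and 46 lost it at least once; genes given only in the closing paragraphs were not counted.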

Other observations

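All genes and symbol families below were chosen after their values were seen, and the genes stand for themselves: no group of them was tested.

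Of 1177 called genes 974 were in none of the 29 lists. Among those that rose were CLGN, a chaperone of the endoplasmic reticulum (4.11-fold, limma adjusted p = 0.00324), EAF2, an elongation factor partner (3.31-fold), NFIL3, a bZIP transcription factor (3.11-fold), and S100P, a calcium-binding protein (2.86-fold). HSPA13, an HSP70 family member, rose 2.84-fold, FICD, which modifies the chaperone HSPA5, 2.69-fold, and EIF2AK3, which encodes the stress kinase PERK, 2.52-fold (adjusted p = 0.00167). The prion protein gene PRNP rose 2.41-fold, CCNA1, cyclin A1, 2.32-fold, and HBEGF, a ligand of the epidermal growth factor receptor, 2.31-fold. CLGN and CCNA1 rose from 3.78 and 4.10, within the range of the dimmest 2393 genes, so the size of their rise is uncertain. SAT1, an enzyme of polyamine breakdown, rose 2.13-fold, TGDS, a predicted sugar nucleotide dehydratase, 2.09-fold, SLC33A1, an acetyl-CoA carrier, 1.89-fold, and BORA, an activator of mitotic kinases, 1.88-fold.

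Among those that fell were SKP2, a ubiquitin ligase subunit that marks the inhibitor p27, by 0.90 on the log2 scale (limma adjusted p = 0.00423), HELLS, a chromatin remodeller, and DTL, of replication licensing, by 0.83 each. RHOB, a small GTPase, fell by 0.82 and ID2, an inhibitor of differentiation factors, by 0.81. MAT2A, of S-adenosylmethionine synthesis, fell by 0.68, the mitochondrial citrate carrier SLC25A1 by 0.64, the CTP synthase CTPS1 by 0.63, and BRIP1 and BARD1, partners of BRCA1, by 0.62 and 0.61.

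Of 17 symbol families, histones (0 higher and 10 lower of 49, Fisher exact p = 0.000346, adjusted p = 0.00294) and polymerase subunits (1 higher and 10 lower of 45, Fisher exact p = 0.00352, adjusted p = 0.02) also departed from other genes in their calls. These Fisher p also take genes as independent, and correlation within these families was not estimated. The histone family shares genes with the list of replication-dependent histones, and the polymerase family with that of DNA replication. Their calls are therefore not separate from those of the lists. Some histones were read by probe sets with an x suffix, which can bind other sequences. The median log2 fold change was -0.163 over all histone genes and -0.0981 over all polymerase subunits.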
